A study of Homo sapiens with 4 samples.

How the data were processed

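Total RNA of SH-SY5Y neuroblastoma cells was measured on 4 one-colour Agilent gene expression arrays, 2 of control cells and 2 of cells labelled MBD5-heterozygous, with 1 sample per array. Groups and replicate numbers were taken from the sample titles. The design text calls the replicates biological, and how the cultures or clones were kept apart is not given in the sources used here. Per the labels' protocols, the RNA was purified on columns with DNase and turned into Cy3-labelled cRNA. All 4 arrays came from 1 slide and 1 scan, per the file headers, so neither slide nor scan separated the groups.

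Per the file headers and the submitters' processing notes, the arrays were read with Agilent Feature Extraction 11.0.1.1, and the scanner files hold linear intensities of each spot. Per the file headers, the processed signal is background-subtracted with spatial detrending within each array and is not normalized between arrays, and low spots carry a small positive surrogate value. The deposited table of processed values also holds linear intensities. Set against the scanner files, each of its columns equalled the mean processed signal of a probe divided by 1 constant per array, close to the 75th percentile over probe means, with no log and no centring of genes, and in the direction of the scanner values. It holds 23774 probes (69.7%), and why these were kept is not given in the sources used here. The medians of its columns are 0.367 and 0.365 for control replicates 1 and 2 and 0.379 and 0.377 for heterozygous replicates 1 and 2.

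Each array carried 43118 spots that were not controls, for 34127 probes, of which 999 were printed in 10 spots. Spots marked as outliers by the scanner software (404 and 487 on the control arrays, 467 and 417 on the heterozygous arrays) were left out, and control spots were not used. The log2 processed signal was taken relative to the 75th percentile of each array, and spots of a probe were averaged. A probe was kept if over a share of 0.5 of its spots were well above background on both arrays of at least 1 group, which 22744 probes passed. The files give no gene name, so probes were named through their transcript accession in the RefSeq gene table of a later human assembly, which gave 25771 probes (75.5%) a symbol and left 8356 without. That table was used only for names and gene order, because the array design is annotated on an earlier build, and no coordinates are given. Probes designed on Ensembl transcripts, those of the mitochondrial genome among them, stayed unnamed. For each gene the kept probe with the highest mean signal was tested, which gave 18251 features, 14495 with a symbol and 3756 under an accession or probe name. Of 1190 further probes of 1032 called genes, 136 had the opposite sign and 15, each of a different gene, passed with the opposite sign.

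Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The fit had 2 residual and 1.97 prior degrees of freedom, and the median standard error of a log2 fold was 0.07. Gene lists with at least 4 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01. They were tested again with an estimated correlation, with which 0 lists passed. Both were adjusted over the 40 lists tested. The estimated version rests on the 2 residual degrees of freedom and has little power here. The noradrenergic list, with an estimate of 0.00223, below the preset, went from an unadjusted camera p of 0.00295 to 0.0842. Other estimates ran from -0.211 for complex II to 0.469 for histones. A call lost with the estimate is therefore not by itself a sign of high correlation. Counts adjusted over the list alone use the same limma p values. Where a gene was not well above background on any array of a group, only a bound is given. It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the gene's own value and the lowest value of any probe well above background on that array. A list's median uses the measured values, and a median with bounds, given where it differed, puts the bound in place of them.

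The groups, the tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule named MBD5 and MBD6, the 12 largest rises and 12 largest falls among called genes with a symbol, and up to 4 members with the smallest p in each list; some genes that the rule names are not reported here. The 12 largest rises and falls among genes measured on all 4 arrays were added after the data were seen, because values at the background have no order. Every other gene named as a list member, such as COL1A1, COL1A2, TWIST1, VIM, HAND2, GATA3, TRAP1, SUCLG2, TK2, TOP1MT, LRPPRC, PPRC1, PFKFB2, PFKP, NUPR1, CEBPB, AEN, SESN1, CBX2, PCGF6, SPRY4, KLF6, ATF3, ORC4, KIF5C, ACVR2A, EPC2, RORA, PRDX3 and GLRX2, was chosen after its values were seen. The 41 lists covered the respiratory chain (together and as complexes I to V), its assembly factors, mitochondrial DNA-encoded genes, mitochondrial ribosomal proteins, the tricarboxylic acid cycle, mitochondrial biogenesis, dynamics, fatty acid oxidation and unfolded protein response. They also covered glycolysis, hypoxia, cholesterol biosynthesis, the integrated stress response, chaperones, p53 and NRF2 targets, antioxidant enzymes, interferon response, antigen presentation, immediate early and clock genes. The rest were proliferation, histones, cytosolic ribosomal proteins, PR-DUB, both Polycomb complexes, methyl-CpG-binding genes, syndromic chromatin genes, HOX genes, genes around MBD5, noradrenergic, mesenchymal, glial, synapse and axon guidance genes. On the array, 97.6% of the list members had a probe. The list of mitochondrial DNA-encoded genes had no named probe and was not tested.

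Replicate arrays were compared before they were averaged. The median size of the log2 difference was 0.105 between the control arrays, 0.0457 between the heterozygous arrays and 0.183 to 0.201 between groups. Over 723 probes printed in 10 spots, the variance between arrays was 14.4 times that expected from the spots for the control arrays and 2.37 times for the heterozygous arrays. Labelling and hybridization alone can give such a difference, so it does not show separate cultures. Each array was counted as a sample of its own because the deposited design calls the replicates biological, and p measures only the spread between these samples, which may be technical.

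The steps were tested on simulated data with the real arrays' means and spread, in 5 runs over 18248 genes with 200 changed genes each, for this comparison. Of 250 genes changed 1.25-fold, 0 were recovered with the right direction and 1 was called in the wrong one. The share recovered was 8% at 1.5-fold, 69.2% at 2-fold and 92.4% at 4-fold, and 0.0212% of unchanged genes were called. Of 170 lists without a shift, 0 were called, and a list shifted by -0.1 was called in 5 of 5 runs. Genes were drawn independently, with no correlation between them and no shift tied to signal or scaling. False list calls from those sources were therefore not tested. Far more genes were called in the data (27.8%) than were changed in a run, so the recovered shares need not carry over. The alternatives were quantile normalization, centring on the median, normexp background correction with an offset of 50, the deposited table, no filter on dim probes, a filter for genes well above background on all 4 arrays, outlier spots kept, the mean over a gene's probes, every probe on its own, eBayes with trend and robust options, the replicate number as a block, each array left out in turn, and for lists an estimated correlation and fry. Normexp had been planned on mean spot signals and was run on median spot signals, the raw foreground used here.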

Results

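The data were 4 one-colour oligonucleotide arrays of total RNA from SH-SY5Y, a human neuroblastoma cell line that is used as a model of catecholaminergic neurons. Of these, 2 arrays came from control cells and 2 from cells labelled MBD5-heterozygous, and the design text calls the 2 replicates of each condition biological. MBD5 and its paralogue MBD6 encode methyl-CpG-binding-domain proteins that associate with the PR-DUB deubiquitinase complex of chromatin, and loss of a copy of MBD5 in people causes a neurodevelopmental disorder. The comparison asked how the transcriptome of the heterozygous cells differed from that of control cells, and the title of the series points to mitochondrial respiration and chromatin. The 75th percentile of spot signal was 1173 and 1027 on the control arrays and 1093 and 1015 on the heterozygous arrays, and between 67% and 68.9% of spots were well above background, with 0 saturated spots. Over the tested genes, Pearson's r across genes was 0.998 between the control arrays, 0.999 between the heterozygous arrays and 0.979 to 0.980 between arrays of different groups; genes are not independent replicates. The number of arrays limits the precision, and whether the heterozygous arrays came from 1 or several edited clones is not given in the sources used here.

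MBD5 itself did not differ detectably between the groups. Its probe read -2.70 ± 0.0016 (SD, n = 2) in control cells and -2.68 ± 0.05 in the arrays labelled MBD5-heterozygous, in log2 units relative to each array's 75th percentile. The log2 fold was 0.02 ± 0.05 (SE; limma adjusted p = 0.762), with a 95% confidence interval from -0.12 to 0.17, and its sign turned under 4 alternative settings. The interval excludes a 2-fold fall of the MBD5 transcript at this probe. Where the edit lies relative to the probe is not given in the sources used here. An edit that leaves the transcript level unchanged would not show at a probe outside the edited part. The labels of the heterozygous arrays therefore rest on the deposited descriptions. MBD6 gave a log2 fold of -0.02 ± 0.08 with its brighter probe (limma adjusted p = 0.861), of a sign that turned under 2 settings, and -0.40 with its dimmer probe.

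The changes in other genes were many and, at the top, very large. In all values below, ± is the standard error of the log2 fold with n = 2 arrays per group, and a positive value is higher in the arrays labelled MBD5-heterozygous. Among genes measured on all 4 arrays, the largest rises were those of LRRC17, at 6.81 ± 0.09, TSPAN8, a tetraspanin, at 6.22 ± 0.05, and the secreted protease HTRA1, at 5.96 ± 0.06. They were followed by SPARCL1 (5.32 ± 0.05), IGFBP3 (5.25 ± 0.05), the gap-junction gene GJA1 (5.09 ± 0.12), IL4R (5.06 ± 0.10), the hyaluronan receptor CD44 (4.81 ± 0.06), TNFRSF1A (4.79 ± 0.13), COL3A1 (4.68 ± 0.07), S100A10 (4.67 ± 0.05) and GFRA2 (4.59 ± 0.05). Other genes rose from a control signal that was not well above background, which gives only a lower bound. The zinc-finger transcription factor ZIC5 was at least 70.1-fold higher, CYB5R2 and RAB7B each at least 33.8-fold, AMIGO2 at least 32.0-fold, the hyaluronan synthase HAS2 at least 27.1-fold, FRMD4B at least 23.7-fold, WFDC1 at least 21.9-fold and RBM24 at least 12.1-fold. TLR4, which was well above background on 1 of the 2 control arrays, rose by 6.81 ± 0.31 at its measured values. Its other probe, not well above background on either control array, read 4.11. The limma adjusted p of the rises named in this paragraph lay between 9.36e-05 and 0.00107.

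**Figure D1:**
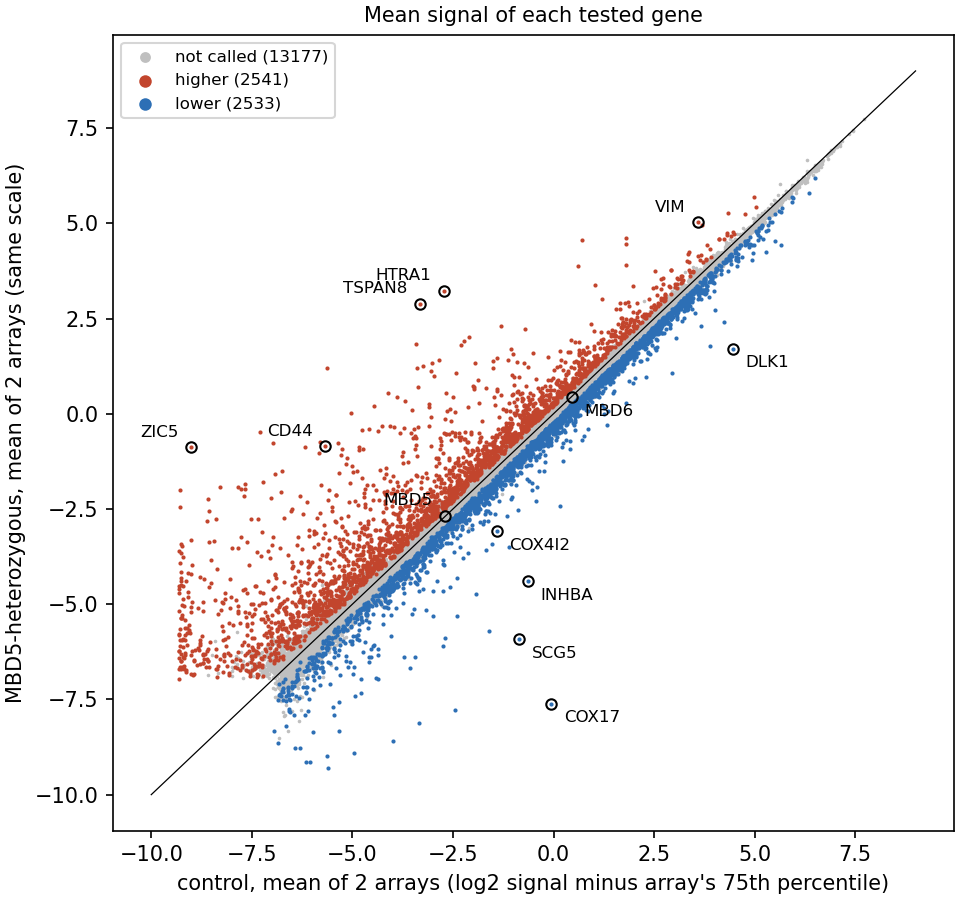
Mean log2 signal of each of the 18251 tested genes in control cells (horizontal axis) and in the arrays labelled MBD5-heterozygous (vertical axis), each a mean of 2 arrays relative to the array's 75th percentile. Red points are the 2541 genes called higher, blue points the 2533 called lower and grey points genes not called; genes below background are plotted at their measured values, so their distance from the diagonal is not a fold.

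The largest fall was that of COX17, which encodes the copper chaperone for assembly of cytochrome c oxidase. Its signal was -0.06 ± 0.11 (SD, n = 2) in control cells and was not well above background on either heterozygous array, at least 124-fold lower (limma adjusted p = 0.000202). RNF212 was likewise at least 23.7-fold lower, CBLN4 at least 12.7-fold, NEXMIF at least 8.13-fold, EYA2 at least 4.15-fold, ST8SIA4 at least 2.65-fold, IMPA2 at least 2.62-fold and CRH, the corticotropin-releasing hormone gene, at least 1.95-fold. Among genes measured on all 4 arrays, the largest falls were those of the secretory-granule chaperone SCG5 (-5.07 ± 0.05), the activin subunit gene INHBA (-3.77 ± 0.05), TNFAIP6 (-3.34 ± 0.06) and CPED1 (-3.18 ± 0.05). The thyroid hormone deiodinase DIO3 (-2.93 ± 0.32), the netrin receptor UNC5D (-2.91 ± 0.06), ARHGAP36 (-2.80 ± 0.06), DLK1 (-2.74 ± 0.07), NEDD9 (-2.66 ± 0.20), HEBP2 (-2.58 ± 0.12), TES (-2.39 ± 0.09) and ITGB5 (-2.30 ± 0.05) also fell. The second probe of ST8SIA4, for another transcript, was below background on all 4 arrays.

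**Figure D2:**
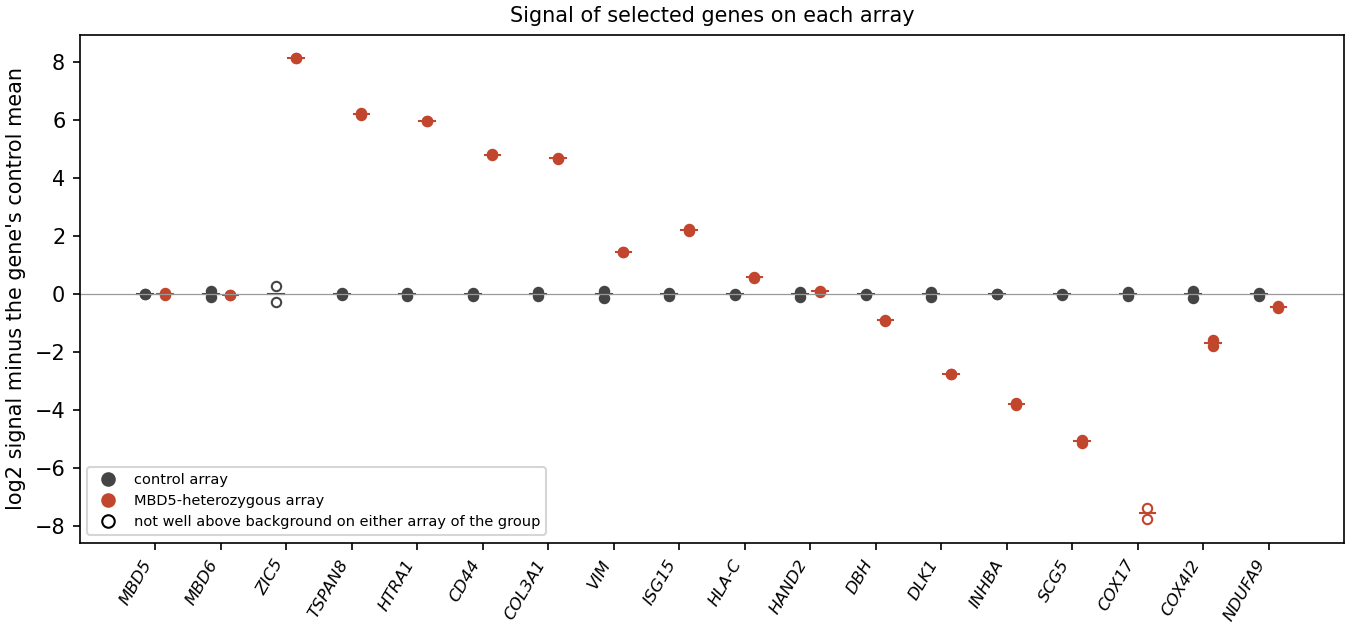
Log2 signal of 18 genes on each of the 4 arrays, relative to the gene's mean in control cells (vertical axis); dark points are control arrays, red points arrays labelled MBD5-heterozygous, and short lines group means. Open points mark a group in which the gene was not well above background, drawn at the measured values: ZIC5 in control cells and COX17 in the heterozygous arrays, for which only the bounds of at least 70.1-fold and at least 124-fold hold.

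Over all 18251 genes tested with limma, 2541 were higher and 2533 lower in the arrays labelled MBD5-heterozygous at an adjusted p under 0.05, or 27.8% of those tested. The rises were the larger changes. Of the called genes, 818 rises and 153 falls reached 2-fold on the fitted scale, and 268 of the rises and 63 of the falls met a group that was not well above background. All 5074 called genes had groups that did not overlap, as did 71% of the tested genes, where chance gives 33.3%. At 2-fold or more with separate groups there were 1021 genes (852 higher, 169 lower), against 390 with normexp background correction, 638 when a gene had to be well above background on all 4 arrays and 1532 with no filter on dim probes. The split between rises and falls depended on the scale: 50.1% of the calls were rises, but 25.8% when each array was centred on its median (1963 higher, 5647 lower), a change that moved the median log2 fold of all genes by -0.117 from -0.05. Without heterozygous replicate 1 the calls numbered 1098 higher and 378 lower, without heterozygous replicate 2 they numbered 1114 and 332, and with no filter on dim probes 1356 and 639. The 12 largest rises and 12 largest falls, overall and among genes measured on all 4 arrays, kept their calls with any array left out and with no filter. Of 264 called members of the gene lists with a log2 fold under 1 in size, 30 and 30 were called with heterozygous replicate 1 or 2 left out in turn. Of 167 called genes named by rule, 76 and 77 lost the call without heterozygous replicate 1 or 2, 54 with no filter, 16 under quantile normalization, 14 with the replicate block and 8 and 4 without control replicate 1 or 2. Among them, NDUFV3, COX6B2, YME1L1, SUZ12, RBBP4 and CRY2 each lost the call in 6 settings. Of the 80 counts of higher or lower members in the 40 tested lists, some moved by over 1.5 times and at least 2 genes. There were 33 such counts with no filter, 23 under median centring, 16 with the trend and robust options of eBayes and 10 under quantile normalization. Many counts also moved when heterozygous replicate 1 or 2 was left out.

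Genes of mesenchymal cells and fibroblasts rose together. SH-SY5Y is a noradrenergic derivative of a line that also contained substrate-adherent (S-type) cells with mesenchymal features. Of 29 markers of such cells on the array, 23 passed the filter, 4 of them not well above background in 1 of the groups. Of these 23 tested markers, 19 rose and 2 fell, and 20 rose and 2 fell when adjusted over the list alone. The median log2 fold was 2.07, or 2.04 with bounds (camera adjusted p = 5.59e-13; adjusted p = 0.361 with an estimated correlation). CD44, COL5A1 and the calcium-binding protein gene S100A6 rose by 4.81 ± 0.06, 4.37 ± 0.06 and 4.10 ± 0.06, and ANXA1 was at least 6.44-fold higher. COL1A1 rose by 3.62 ± 0.05 while COL1A2, which encodes the partner chain of the same collagen, fell by 1.17 ± 0.05, and TWIST1 fell by 0.22 ± 0.05. These 3 genes and vimentin (VIM) were chosen after their values were seen. Vimentin, abundant in both groups, rose by 1.45 ± 0.09. All 15 Schwann cell and glial markers of the list were on the array, and 6 passed the filter. With no filter 15 were tested, 3 rose and 0 fell, and the median was 0.0196. Of the 6, 4 rose and 0 fell (4 and 1 when adjusted over the list alone), with a median of 0.74. The camera adjusted p of the 6 was 0.0362 (adjusted p = 0.408 with an estimated correlation). Among the rises were the myelin gene PMP22 (0.79 ± 0.05), the neurotrophin receptor NGFR (1.85 ± 0.12) and EGR2 (0.68 ± 0.14). The EGR2 call ended under quantile normalization (adjusted p = 0.0684), with no filter (0.119) and without heterozygous replicate 1 (0.0897), control replicate 1 (0.0939) or control replicate 2 (0.115). The call of this list ended under quantile normalization (adjusted p = 0.114), with no filter (0.0852), with only genes measured on all 4 arrays (0.0894) and without control replicate 2 (0.0943).

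Of 43 axon guidance and cell adhesion genes on the array, 31 passed the filter. Among these 31, 11 rose and 7 fell (15 and 7 when adjusted over the list alone). NRP1, a receptor for semaphorins, rose by 2.54 ± 0.06 and PLXNA4 by 0.96 ± 0.05 (0.45 and 0.47 with other probes), while UNC5D fell by 2.91 ± 0.06 and the ephrin EFNB2 fell by 1.10 ± 0.05. The list's median was 0.27 (camera adjusted p = 0.0213; adjusted p = 0.361 with an estimated correlation), and its call ended under quantile normalization (adjusted p = 0.0686). Of 38 synapse and axon genes, 9 rose and 15 fell (10 and 15 when adjusted over the list alone). The median was -0.08, and the list did not pass (camera adjusted p = 0.736). RBFOX3, a splicing factor of mature neurons, rose by 3.80 ± 0.18, SYT4 by 2.09 ± 0.07 and NLGN1 by 2.07 ± 0.08, whereas doublecortin (DCX) fell by 0.89 ± 0.05. With heterozygous replicate 1 or 2 left out, 6 and 6 guidance genes remained called higher and 4 and 4 lower, and 4 and 5 synapse genes higher and 5 and 4 lower.

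Genes of noradrenergic identity and catecholamine synthesis were lower as a list. Of 25 tested, 12 fell and 1 rose (13 and 1 when adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.00893; adjusted p = 0.361 with an estimated correlation). DLK1 (-2.74 ± 0.07), the vesicular monoamine transporter SLC18A1 (-1.49 ± 0.08) and dopamine beta-hydroxylase (DBH, -0.90 ± 0.05) were among those that fell, while TBX2 rose by 0.87 ± 0.06. The lineage factors HAND2 and GATA3 had log2 folds of 0.10 ± 0.08 and 0.07 ± 0.05, and neither passed. The list's call ended under quantile normalization (adjusted p = 0.0686), and with heterozygous replicate 1 or 2 left out in turn 5 and 5 falls were called.

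Interferon-response genes and genes of MHC class I antigen presentation were higher. On the array were 25 interferon-response genes of the list, and 20 passed the filter. Of 20 tested interferon-response genes, 16 rose and 0 fell (18 and 0 when adjusted over the list alone), with a median of 0.62, or 0.58 with bounds (camera adjusted p = 2.4e-10; adjusted p = 0.361 with an estimated correlation). The ubiquitin-like modifier ISG15 rose by 2.22 ± 0.06 and IFIT1 by 1.80 ± 0.05, and IFIT3 and IFI44L were at least 2.11-fold and 1.29-fold higher. Of 15 antigen presentation genes, 8 rose and 0 fell (10 and 0 when adjusted over the list alone), with a median of 0.57, or 0.38 with bounds for genes at background (camera adjusted p = 2.28e-05; adjusted p = 0.361 with an estimated correlation). HLA-C rose by 0.58 ± 0.05, the peptide transporter subunit TAP2 by 1.04 ± 0.09 and the aminopeptidase ERAP2 by 2.73 ± 0.12, from a level well above background on 1 of 2 control arrays; the immunoproteasome subunit PSMB8 was at least 1.23-fold higher. Leaving out heterozygous replicate 1 or 2 in turn, the rises called were 8 and 8 for the interferon list and 5 and 4 for antigen presentation.

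Nuclear genes of the mitochondrial respiratory chain shifted down slightly, on the scale used here. Of 83 tested subunits of complexes I to V, 10 fell and 0 rose. That is no excess of falls, since 2533 of all 18251 tested genes fell. When adjusted over the list alone, 1 subunit fell. Log2 folds were negative for 79 subunits and positive for 4, the highest 0.40 for a complex I subunit that did not pass. The median was -0.11, against -0.05 for all genes and -0.08 for random lists matched on signal, and the list passed (camera adjusted p = 0.000158; adjusted p = 0.411 with an estimated correlation). Under quantile normalization the median was -0.0038, the direction of the test was upward and the call ended (adjusted p = 0.959). COX4I2, an alternative subunit of complex IV, fell by 1.67 ± 0.12 and the complex I subunit NDUFA9 fell by 0.44 ± 0.06. The ATP synthase subunits ATP5F1C and ATP5F1B fell too, at -0.39 ± 0.06 and -0.34 ± 0.05. By complex, 6 of 37 complex I genes fell and 0 rose (0 and 0 when adjusted over the list alone), with NDUFB8 and NDUFS6 each at -0.27 ± 0.05 and NDUFV3 at -0.24 ± 0.05. The complex I list passed (median -0.13, camera adjusted p = 0.00107; adjusted p = 0.408 with an estimated correlation), except under quantile normalization (adjusted p = 0.833). Complexes II, III, IV and V did not pass, with camera adjusted p of 0.181, 0.181, 0.115 and 0.0598. Their medians were -0.18, -0.10, -0.07 and -0.10, the latter pair turning positive under quantile normalization, and 0 of 4, 0 of 9, 2 of 15 and 2 of 18 genes fell (0, 0, 1 and 2 when adjusted over each list alone). The complex IV falls were COX4I2 and COX6B2, at -1.67 ± 0.12 and -0.25 ± 0.05. Named members that missed the threshold were SDHB (-0.21), SDHA (-0.15), SDHD (-0.51 ± 0.26) and SDHC (-0.08) of complex II, CYC1 (-0.20), UQCRFS1 (-0.15), UQCRC1 (-0.20) and UQCR10 (-0.10) of complex III, COX4I1 (-0.20) and COX5A (-0.32 ± 0.13), and ATP5PB (-0.22) and ATP5MF (-0.17). SDHC and UQCR10 turned positive under quantile normalization. Under median centring 10 of these 12 were called lower, all but SDHD and UQCRC1, with the trend and robust options of eBayes 7 and with normexp 5, and without control replicate 1 so were CYC1 and UQCRC1 (adjusted p = 0.0435 and 0.0378). With the replicate number as a block COX5A was called lower, and with only genes measured on all 4 arrays ATP5PB and COX4I1 were. The other SDHA probes read -0.43, -0.35 and -0.37, and with the mean over its probes SDHA was called at -0.33 (limma adjusted p = 0.0172). The other probes of SDHC read -0.23 and 0.04. The SDHD log2 fold came from 1 array: it was -0.87 and called without heterozygous replicate 2 (adjusted p = 0.0267) and -0.15 without heterozygous replicate 1, and the other SDHD probes read -0.03 and -0.14. No probe on the array was named for the 13 genes encoded in mitochondrial DNA. Without heterozygous replicate 1 or 2, 1 and 1 of the 10 falls stayed called in the whole list, and 0 and 0 of the 6 in complex I.

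Assembly factors and mitochondrial ribosomal proteins also shifted down slightly. Of 44 assembly factors 9 fell and 0 rose (2 and 0 when adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.00523; adjusted p = 0.361 with an estimated correlation). Apart from COX17, the falls were small, at -0.38 ± 0.05 for COA1, -0.37 ± 0.08 for NDUFAF4 and -0.26 ± 0.05 for ACAD9. Of 79 mitochondrial ribosomal proteins 16 fell and 0 rose (0 and 0 when adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.000158; adjusted p = 0.361 with an estimated correlation). MRPL23 and MRPS7 stood at -0.45 ± 0.05 and -0.45 ± 0.06, and MRPL20 and MRPS30 each at -0.30 ± 0.05. Of 17 genes of the mitochondrial unfolded protein response, 5 fell and 0 rose (10 and 0 when adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.00596; adjusted p = 0.361 with an estimated correlation). They were the import pore gene TOMM40 (-0.57 ± 0.09), the protease gene LONP1 (-0.41 ± 0.06), GRPEL1 (-0.35 ± 0.06), YME1L1 (-0.26 ± 0.05, or -0.06 with another probe) and, outside the naming rule, TRAP1 (-0.26). Under quantile normalization the calls of the assembly factors, the ribosomal proteins and the unfolded protein response ended, at adjusted p = 0.463, 0.527 and 0.114. Left out in turn, heterozygous replicates 1 and 2 each reduced the called falls to 1 assembly factor (COX17), 0 ribosomal proteins and 0 genes of the unfolded protein response.

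Other mitochondrial lists did not pass. The tricarboxylic acid cycle and pyruvate entry list came closest (median -0.12, camera adjusted p = 0.0518), with 7 of 27 genes lower and 2 higher (9 and 2 when adjusted over the list alone). The pyruvate dehydrogenase kinases PDK1 and PDK4 moved in opposite directions, by -1.28 ± 0.05 and 1.23 ± 0.07, and the pyruvate carrier MPC1 and fumarase (FH) fell, at -0.52 ± 0.06 and -0.34 ± 0.05. SUCLG2, the other rise, stood at 0.53. Of 23 genes of mitochondrial dynamics and mitophagy, 8 fell and 1 rose (8 and 2 when adjusted over the list alone; median -0.07, camera adjusted p = 0.169), among them BNIP3 (-0.77 ± 0.05), BNIP3L (-0.49 ± 0.05), MTFR2 (-0.48 ± 0.08) and PINK1 (0.39 ± 0.06). Of 24 genes of mitochondrial biogenesis and DNA maintenance, 5 fell and 3 rose, also when adjusted over the list alone (median -0.11, camera adjusted p = 0.267). The coactivator PPARGC1B rose by 0.86 ± 0.05, with TK2 at 0.66 and TOP1MT at 0.29. GABPB1 (-0.46 ± 0.05), TFB1M (-0.41 ± 0.08), NRF1 (-0.40 ± 0.08), LRPPRC (-0.27) and PPRC1 (-0.24) fell. Of 22 fatty acid oxidation genes, 7 fell and 0 rose (7 and 1 when adjusted over the list alone; median -0.05, camera adjusted p = 0.267), with HADH and ETFA at -0.37 ± 0.07 and -0.37 ± 0.06, DECR1 at -0.33 ± 0.05 and ETFB at -0.30 ± 0.05. In the absence of heterozygous replicate 1 or 2, 1 and 1 cycle genes, 1 and 1 dynamics genes, 0 and 0 biogenesis genes and 0 and 0 oxidation genes were called lower.

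Glycolytic and hypoxia-inducible genes were lower. Of 22 glycolysis genes 13 fell and 3 rose (16 and 3 when adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.00108; adjusted p = 0.454 with an estimated correlation). Aldolase C (ALDOC, -0.96 ± 0.06), hexokinase 2 (HK2, -0.64 ± 0.05) and lactate dehydrogenase A (LDHA, -0.63 ± 0.05) fell, and the rises were the lactate exporter SLC16A3 (1.20 ± 0.10), PFKFB2 (0.42) and PFKP (0.34). Of 18 hypoxia targets 10 fell and 2 rose (11 and 3 when adjusted over the list alone), with a median of -0.34 (camera adjusted p = 0.0267; adjusted p = 0.408 with an estimated correlation). PDK1 (-1.28 ± 0.05), BNIP3 (-0.77 ± 0.05), HK2 (-0.64 ± 0.05) and the collagen prolyl hydroxylase P4HA1 (-0.60 ± 0.06) were among the falls. EGLN3 and ANGPTL4, named like PFKFB2 and PFKP after their values were seen, rose by 0.46 and 0.59. The hypoxia call ended under quantile normalization (adjusted p = 0.129), median centring (0.0588), the mean over a gene's probes (0.0659), every probe on its own (0.0604) and without control replicate 2 (0.0508). Without heterozygous replicate 1 or 2, 3 and 2 glycolysis genes and 3 and 3 hypoxia targets were called lower.

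Genes of cholesterol biosynthesis were lower. Of 23 tested genes 18 fell and 0 rose (20 and 0 when adjusted over the list alone), with a median of -0.34 (camera adjusted p = 5.96e-06; adjusted p = 0.361 with an estimated correlation). MVD and MSMO1 each fell by 0.65 ± 0.06, and mevalonate kinase (MVK) stood at -0.56 ± 0.05. Of 32 genes of the amino acid and integrated stress response 16 fell and 3 rose (19 and 4 when adjusted over the list alone), with a median of -0.30 (camera adjusted p = 0.0246; adjusted p = 0.491 with an estimated correlation). VLDLR (-0.60 ± 0.05, or -0.25 with another probe), the serine synthesis gene PSAT1 (-0.54 ± 0.05) and the mitochondrial folate enzyme gene MTHFD2 (-0.53 ± 0.05) fell, while the glycine transporter SLC6A9 (0.89 ± 0.06), NUPR1 (0.79) and CEBPB (0.33) rose. Of 24 heat shock and endoplasmic reticulum chaperones 6 fell and 0 rose, also when adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.0126; adjusted p = 0.361 with an estimated correlation). DNAJA1, HSPA8, PDIA6 and MANF fell, at -0.55 ± 0.06, -0.48 ± 0.06, -0.45 ± 0.05 and -0.32 ± 0.05. The stress response call ended under quantile normalization (adjusted p = 0.0686), median centring (0.0702) and without control replicate 2 (0.062), and the chaperone call under quantile normalization (0.527). Without heterozygous replicate 1 or 2, the falls called were 0 and 1 for cholesterol biosynthesis, 0 and 0 for the stress response and 0 and 0 for chaperones.

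Proliferation genes were lower by a small amount. Of 33 tested, 18 fell and 0 rose (22 and 1 when adjusted over the list alone), with a median of -0.29 (camera adjusted p = 9.86e-06; adjusted p = 0.361 with an estimated correlation). The ribonucleotide reductase subunit RRM2 (-0.79 ± 0.06), PCNA (-0.56 ± 0.05), CDC6 (-0.52 ± 0.05) and the replicative helicase subunit MCM4 (-0.48 ± 0.05) were among them. Of 11 replication-dependent histone genes 6 fell and 1 rose (9 and 1 when adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.0126; adjusted p = 0.491 with an estimated correlation). H3C4, H2BC11 and H1-2 fell, at -0.47 ± 0.05, -0.42 ± 0.05 and -0.36 ± 0.06, and H2BC12 rose by 0.96 ± 0.07 with its reported probe but read -0.20 with another. Of 23 p53 targets 7 rose and 2 fell (8 and 2 when adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.00893; adjusted p = 0.361 with an estimated correlation). SPATA18 rose by 1.70 ± 0.09, the death receptors FAS and TNFRSF10B by 1.01 ± 0.06 and 0.53 ± 0.05, and TP53I3 by 0.63 ± 0.05, and the falls were AEN and SESN1, each at -0.36. The cell-cycle inhibitor CDKN1A, named after its value was seen, had a log2 fold of 0.20 that did not pass. With heterozygous replicate 1 or 2 removed, the calls numbered 1 and 1 falls for proliferation, 0 and 0 falls for histones and 3 and 2 rises for p53 targets.

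Chromatin genes changed little. In the PR-DUB complex, to which MBD5 and MBD6 belong, 0 of 12 genes passed, also when adjusted over the list alone (median -0.04, camera adjusted p = 0.826), and UBE2O, ASXL2, ASXL3 and HCFC1 had log2 folds of -0.20, 0.14, -0.12 and -0.19. Under other settings UBE2O was called lower without control replicate 2 (-0.24, adjusted p = 0.0446) and in 3 more, HCFC1 without control replicate 1 (-0.34, adjusted p = 0.0385), where BAP1 was called lower too, and ASXL3 under median centring (-0.24, adjusted p = 0.0329). Polycomb repressive complex 2 had 4 of 12 genes lower and 0 higher (5 and 0 when adjusted over the list alone; median -0.14, camera adjusted p = 0.0762): EZH2 (-0.33 ± 0.07), PHF19 (-0.31 ± 0.05), RBBP4 (-0.30 ± 0.07) and SUZ12 (-0.22 ± 0.05). Another probe of RBBP4 read 0.00. Polycomb repressive complex 1 had 4 of 23 lower and 2 higher, also when adjusted over the list alone (median -0.11, camera adjusted p = 0.351), with RYBP (-0.30 ± 0.05), BCOR (-0.28 ± 0.05), CBX2 (-0.24) and PCGF6 (-0.24) lower and PHC3 (0.27 ± 0.05) among the higher. Among 18 methyl-CpG-binding and DNA methylation genes, UHRF1, TET1 and DNMT1 fell (-0.40 ± 0.05, -0.29 ± 0.05 and -0.28 ± 0.05) and BAZ2B rose by 0.32 ± 0.06, the same counts of 3 and 1 as when adjusted over the list alone (median -0.07, camera adjusted p = 0.768). Among 24 chromatin genes of other neurodevelopmental syndromes, UBE3A and TCF4 fell (-0.43 ± 0.06 and -0.39 ± 0.05), KMT2D rose by 0.23 ± 0.05, and ADNP, at -0.20 ± 0.05, did not pass, though 3 other settings called it lower (2 lower and 0 higher when adjusted over the list alone; median -0.02, camera adjusted p = 0.913). Of 14 tested HOX genes 2 rose and 1 fell, also when adjusted over the list alone, namely HOXD10 (0.77 ± 0.07), HOXD8 (0.39 ± 0.07) and HOXD1 (-0.60 ± 0.07). The HOXD1 call ended with normexp and with no filter, and the HOXD8 call with no filter. HOXC8, not well above background on the heterozygous arrays, did not pass (adjusted p = 0.0817), and neither did the list (median -0.04, camera adjusted p = 0.998). HOXC8 was called lower without control replicate 1 or 2 (adjusted p = 0.0271 and 0.00977), under quantile normalization (0.0313) and under median centring (0.0373). With heterozygous replicate 1 or 2 left out in turn, 0 genes of these lists were called except HOXD10.

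A fixed list of genes from the wider region around MBD5 on chromosome 2 was lower. All 20 were on the array, and 16 passed the filter. Of 16 tested, 9 fell and 0 rose (10 and 1 when adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.00893; adjusted p = 0.41 with an estimated correlation). TNFAIP6, a hyaluronan-binding protein gene, fell by 3.34 ± 0.06, and RIF1 and RND3 stood at -0.48 ± 0.07 and -0.35 ± 0.05. ZEB2 fell by 0.45 ± 0.07 with its brighter probe and read 0.05 with another. These 4 genes lie more than 20 genes from MBD5 in the reference's gene order. Of the 5 measured genes within 20, ORC4 and KIF5C fell (-0.37 ± 0.07 and -0.31 ± 0.05), while ACVR2A (-0.46 ± 0.17), EPC2 (-0.00 ± 0.05) and MBD5 itself did not pass. The call ended when every probe was tested on its own (adjusted p = 0.108), and with heterozygous replicate 1 or 2 left out in turn TNFAIP6 was the only member called.

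The remaining lists did not pass as sets, though single members changed. Among 17 immediate early genes, FOS (1.10 ± 0.13), SPRY4 (0.80), EGR2 (0.68, with a call that depended on the setting as above), JUN (0.65 ± 0.05) and KLF6 (0.29) rose, DUSP6 fell by 0.77 ± 0.06, ATF3 fell by 0.30 and KLF2 was at least 1.82-fold lower. These were 5 higher and 3 lower genes (5 and 4 when adjusted over the list alone; median 0.03, negative under median centring and without control replicate 2, camera adjusted p = 0.498). Of 17 circadian clock genes 3 fell and 2 rose (4 and 2 when adjusted over the list alone; median -0.08, camera adjusted p = 0.768). RORB (-1.34 ± 0.07), BMAL1 (-1.28 ± 0.05) and RORA (-0.57) fell, while NPAS2 and CRY2 rose by 1.91 ± 0.26 and 0.24 ± 0.05. Of 21 antioxidant enzymes 3 rose and 3 fell (4 and 5 when adjusted over the list alone; median -0.11, camera adjusted p = 0.838). GPX8, well above background on 1 of 2 control arrays, rose by 5.32 ± 0.29, GLRX by 0.77 ± 0.05 and MGST1 by 0.37 ± 0.06, and TXNRD2 (-0.31 ± 0.05), PRDX3 (-0.24) and GLRX2 (-0.23) fell. Of 18 NRF2 targets 2 rose and 2 fell, also when adjusted over the list alone (median -0.09, mean 0.08, camera adjusted p = 0.871). Heme oxygenase (HMOX1) rose by 1.38 ± 0.05, ABCC2 was at least 2.17-fold higher, and TXNRD1 and SRXN1 fell, at -0.50 ± 0.07 and -0.24 ± 0.05. The ABCC2 call, like that of TXNRD2 above, ended with normexp and with no filter. None of 76 cytosolic ribosomal proteins passed in limma, also when adjusted over the list alone (median -0.04, positive under quantile normalization, camera adjusted p = 0.184), and RPL15, RPL26, RPSA and RPL7 had log2 folds of -0.12, -0.13, -0.10 and -0.09, positive under quantile normalization except for RPL26, and another probe of RPL15 read 0.18. Median centring called 3 of the 76 lower. Of the rises and falls, 2 and 2 immediate early genes, 1 and 2 clock genes, 2 and 0 antioxidant enzymes and 2 and 0 NRF2 targets stayed called without heterozygous replicate 1, and the same numbers without heterozygous replicate 2. Without control replicate 1 the antioxidant and clock falls numbered 5 and 5, and without control replicate 2 the NRF2 falls numbered 4.

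**Figure D3:**
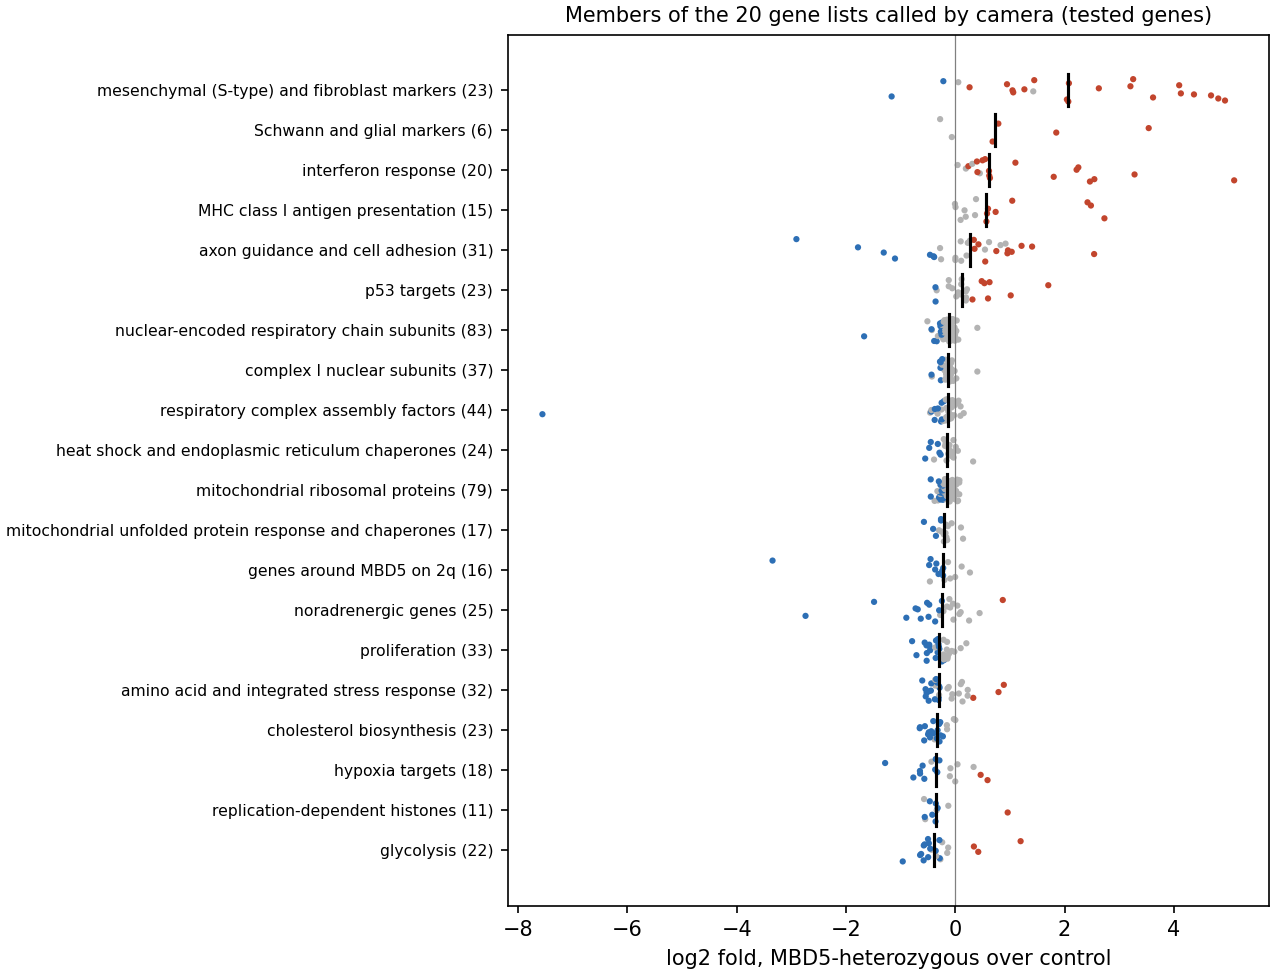
Log2 fold of every tested member of the 20 gene lists that passed camera (horizontal axis), with the number of tested members in parentheses; red points were called higher, blue points lower and grey points neither, and the black bar is the list's median. The medians run from -0.40 for glycolysis to 2.07 for mesenchymal markers, genes below background in a group are drawn and counted at their measured values, and 11 of the 20 calls, the respiratory chain among them with a reversed direction, ended under quantile normalization.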

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

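All the alternatives below were chosen before the data were examined, apart from the use of median spot signals in normexp. The counts of higher and lower genes moved by over 1.5 times with no filter on dim probes (1356 higher, 639 lower) and, for the lower genes, with median centring (5647). Leaving out each array in turn gave 1098 to 2844 higher and 332 to 2928 lower genes, the low ends without a heterozygous array, where the lone array is assumed to vary like the control arrays, which lay further apart (0.105 against 0.0457). The genes at least 2-fold apart with separate groups numbered 390 with normexp, 1532 with no filter and 638 with genes well above background on all 4 arrays. With the replicate number as a block, 2297 genes were higher and 2040 lower, 2162 and 1772 of them shared, and 20 lists passed. No label ties same-numbered arrays, and 2 pairs (deviations correlated at 0.138) are too few to tell, so pairing stays open. A slide or scan block was not run, since all arrays lay on 1 slide.

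The sign of MBD5 turned with quantile normalization (-0.06767), median centring (-0.09399) and normexp (-0.001152), and ranged from -0.01213 to 0.05795 with 1 array left out, never passing. The MBD6 log2 fold read 0.01303 with quantile normalization and -0.1166 to 0.07434 with 1 array left out. Quantile normalization also turned SDHC (0.04571), UQCR10 (0.05181), RPL15 (0.01321), RPSA (0.02684) and RPL7 (0.004964), and the mean over a gene's probes turned RPL15 (0.02635); none of these passed in any of those settings. Over 191 named genes and 2838 pairs of gene and setting, 2522 kept sign and call, 260 lost the call, 44 gained it and 12 changed sign. Quantile normalization left 9 of the 20 list calls, with a respiratory chain median of -0.00379 and an upward test. An estimated correlation, tested on the 2 residual degrees of freedom, left 0. Fry passed 30 lists, all 20 among them, and the NRF2 targets upward (adjusted p = 0.0423) against their median of -0.0874. The other settings kept 17 to 20 of the 20 list calls. Lists gained were complex V and cytosolic ribosomal proteins with median centring, the tricarboxylic acid cycle, complex V and Polycomb repressive complex 2 with normexp, the same 3 with no filter (and complex IV) and with every probe (and complex II), the tricarboxylic acid cycle with the deposited table, and that cycle and complex V without control replicate 1. The cause of these changes was not tested, except that removing an array leaves fewer samples and removing the filter adds dim genes. Signal over background limits the dimmest genes, for which only bounds were given.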

Other observations

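The gene families described first and the tests of a faulty COX17 spot, of fibroblasts and of lineage transcription factors were chosen after the results were seen. All 4 tested ZIC genes, zinc-finger transcription factors of neural development, were higher, in every setting in which they were tested: ZIC1 by 2.55 ± 0.05, ZIC4 by 1.03 ± 0.09, ZIC2 at least 7.26-fold and ZIC5 at least 70.1-fold. Of 8 tested S100A calcium-binding protein genes 7 were higher, among them S100A11 (4.26 ± 0.09), S100A16 (4.16 ± 0.15), S100A13 (2.08 ± 0.05) and S100A2 (1.36 ± 0.05). S100A5 (-0.09) did not pass, and was called lower under quantile normalization and median centring. With no filter on dim probes, 4 of 5 ZIC genes, 7 of 15 S100A genes and 3 of 12 laminin chains were called higher. The S100A median was then 0.359, against 3.09 with the filter. Of 10 laminin chains 8 were higher, or 3 and 3 with heterozygous replicate 1 or 2 left out in turn, with LAMB3 at least 3.77-fold higher and LAMC3, LAMA5 and LAMC1 at 0.86 ± 0.13, 0.72 ± 0.06 and 0.56 ± 0.05.

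Of 26 tested imprinted genes, which are expressed mainly from the copy of 1 parent, 14 fell and 7 rose, or 9 and 3 without heterozygous replicate 1 and 10 and 3 without heterozygous replicate 2. At the DLK1 locus, DLK1, RTL1 and DIO3 fell, at -2.74 ± 0.07, -1.96 ± 0.12 and -2.93 ± 0.32, while MEG3, a noncoding RNA gene of the same locus, read 0.05 ± 0.10. IGF2 and H19, which lie side by side and are expressed from opposite parental copies, both fell, at -1.21 ± 0.05 and -0.99 ± 0.07. GNAS-AS1 (-3.10 ± 0.06), NDN (-1.60 ± 0.07) and PEG10 (-1.29 ± 0.07) also fell, and PHLDA2 (4.34 ± 0.05) and PLAGL1 (0.72 ± 0.07) rose. Of 33 clustered protocadherins 3 rose and 4 fell, with a median of 0.05 that turned to -0.138 under quantile normalization, -0.0709 under median centring and -0.0295 without control replicate 1. The protocadherin rises and falls numbered 8 and 4 without control replicate 2, 2 and 2 without heterozygous replicate 1 and 2 and 4 without heterozygous replicate 2. No enrichment test was run on these families.

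The COX17 signal stood at 1189 and 937 on the control arrays and at 4.84 and 5.98 on the heterozygous arrays. A faulty spot stays open: 0 of the 4 spots were marked as outliers, but a marked spot would have been left out beforehand, and COX17 had 1 probe in 1 spot per array. A deletion reaching the neighbouring genes is argued against: the nearest measured gene on 1 side, CFAP91, read -0.174, and POPDC2 on the other side rose by 0.92, where a fall of at least 1 on both sides had been set as the mark of a deletion. The rise of POPDC2 went past the bound set for no deletion, but upward. A change confined to COX17 or to the sequence under its single probe may account for the loss of signal and stays open, as does a difference between clones or the MBD5 edit itself, none of which was tested.

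Mesenchymal markers rose while many noradrenergic genes fell. Whether fibroblasts were mixed into the culture stays open. Of 22 abundant fibroblast transcripts, COL1A2 (-1.17), LOX (-0.37) and THBS1 (-0.31) fell. CCN2 and POSTN were not well above background on the heterozygous arrays. These 5 go against a plain mixture, but 16 of the 22 rose. The bound of this test was set after the results were seen, so it cannot decide. Of the 22, 10 also belong to the mesenchymal list. A general loss of lineage identity stays open: the 9 lineage transcription factors had a median of 0.0747 with 0 lower and 1 higher, but ran from -0.277 to 0.869 with a spread of 0.337. Another candidate explanation that stays open is a larger share of S-type cells, or a clone of that kind, with the MBD5 edit itself also untested.

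The falls of respiratory chain and mitochondrial ribosomal genes were small, and their calls may come from the scaling between arrays: under quantile normalization the camera p, unadjusted, was 0.911 for the respiratory chain and 0.277 for the ribosomal proteins. The median log2 fold of all genes ran from 0.09 in the dimmest of 10 equal bins of signal to -0.09 in the brightest. Against 10000 random lists matched on signal, the respiratory chain lay at percentile 4.46 and the mitochondrial ribosomal proteins at 0.21, so a shift of bright probes cannot be told apart from a change of the respiratory genes, whose percentile fell between the bounds set. A lower expression of these genes in MBD5-heterozygous cells stays open.

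A hypothesis of a lower copy number of the segment around MBD5 was tested on the 5 measured genes within 20 genes on either side. Their median was -0.307, at percentile 2.24 of 49333 windows, between the bounds set. A loss of a smaller part, on either side of MBD5, is thus not excluded. The windows overlap and were not matched on measured genes, and 5 is the fewest that a ranked window could hold. Medians of few genes vary more, so the percentile may overstate how unusual this window is. MBD5 (0.02 ± 0.05) and EPC2 (-0.00 ± 0.05), which are among the 5, did not fall, which argues against a loss that spans both. In gene order they lie between ORC4 (-0.37 ± 0.07) and KIF5C (-0.31 ± 0.05), the called falls of the window. A single continuous loss that covered both falls would also cover MBD5 and EPC2, so these values argue against it.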
